A study of Homo sapiens with 8 samples.

How the data were processed

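RNA of Caco-2 cells was compared on 8 Agilent 2-colour oligonucleotide arrays. Each array carried the RNA of cells given tocopherol-enriched mixed micelles in 1 dye and the RNA of cells given control micelles in the other, so that each array is its own comparison of treated with control cells. The labels put 4 arrays in the alpha-tocopherol group and 4 in the gamma-tocopherol group, and in each group the treated RNA was Cy5 on 2 arrays and Cy3 on 2. The direction of each ratio was taken from the dyes in the labels.

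The authors deposited the scanner output of each array, which holds spot and background intensity values on a linear scale, produced by Agilent Feature Extraction 9.1.3.1 on array design 014850, per the file headers. These intensity values were not normalized. The same files hold a log10 ratio of Cy5 over Cy3, computed by the scanner software from its own background-subtracted and dye-normalized signals, per the file headers. The authors also deposited a table of log10 ratios for the series. Set against the scanner files, each of its columns equalled that log10 ratio with the sign turned to treated over control where the treated RNA was Cy3, and each column had a median of 0. Its scale and direction were thereby known, and it was used only as an alternative. The arrays were scanned in 2 sessions and on 3 slides, per the file headers. Session 1 held the arrays numbered 1 and 2 of both compounds, and session 2 those numbered 3 and 4. Slide 1 carried alpha replicates 1 and 2 with gamma replicate 2, slide 2 carried all arrays of session 2, and slide 3 carried gamma replicate 1.

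From the deposited intensity values, log2 ratios were computed here. Background was corrected by normexp with an offset of 50 on the mean spot and median background signals, and each array was normalized by loess, with control spots at weight 0. Spots marked as non-uniform or population outliers by the scanner software were left out, so that a probe without another spot had a missing value on that array, and saturated spots were kept. Of 45015 spots, 43376 were not controls, and spots of the same probe were averaged to 41000 probes. A probe was tested when it was well above background in at least 3 of 4 treated channels of a compound or in at least 6 of 8 control channels, which left 23617 probes. Probes were named through a reference gene table of the GRCh38.p14 assembly, used for names only: 23434 probes matched by accession, 2317 by symbol and 1043 by an older symbol, and 14206 did not match and kept the file's name. The table gave 2807 genes another symbol than the file's. Where a gene had several probes, the probe with the highest mean log2 intensity stood for it. This gave 17857 features, of which 11977 carried an official symbol, and 240 features had a missing value on at least 1 array. Among the 137 genes named by rule, 55 had 72 further probes, of which 16 (of 15 genes) gave another call for a compound.

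Differences were tested with limma 3.58.1 in R 4.3.3. All 8 arrays entered 1 linear model with a coefficient for each compound, multiplied by the dye orientation, and a gene-wise dye coefficient. Moderated tests were adjusted by the Benjamini-Hochberg method, and calls were made at an adjusted p of 0.05. The comparisons were alpha-tocopherol against control, gamma-tocopherol against control, and alpha minus gamma. No replicate block was used. Gene lists (27, for lipid handling, stress responses, cell states and other cell types) were tested with camera, which asks whether a list's genes moved relative to all other genes, at a preset correlation between genes of 0.01. The p-values were adjusted over all 81 list tests. Camera was also run with the correlation estimated from the arrays. Fry was run beside it; it asks whether a list's genes moved on balance in 1 direction and does not compare them with other genes. Values given as ± are standard errors of the fit (SE, n = 4 arrays per compound), intervals are 95% confidence intervals, and dye-corrected values of single arrays are their ratios after the fitted dye effect was removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

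The genes named were chosen by a rule. For each compound these were the 12 largest rises and the 12 largest falls among genes with an official symbol, an adjusted p under the threshold and the same sign in all 4 arrays. For alpha minus gamma, the 8 largest differences in each direction were to be named, or the 3 with the smallest p where fewer than 3 passed. Up to 4 members of each list with the smallest p were added, along with a fixed set that held INSIG1, SREBF1, SREBF2, ABCA1, APOA1, NPC1L1, SCARB1, CYP3A4, NQO1, HMOX1 and TTPA whatever their values. TTPA was not among the tested features. Some genes that the rule names are not reported here. Grouping, tests, lists, the naming rule and most alternatives were fixed before the data were examined. The cholesterol and sterol lists were known to be a topic of the study's paper, so they are not independent evidence of a direction.

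The tests were checked on simulated arrays with each gene's residual spread in the real ones, taken as equal on all arrays. Among 17857 features, 50 were changed at each of 4 fold sizes. For alpha, 12% of genes changed 1.1-fold, 68% changed 1.25-fold, 88% changed 1.5-fold and 100% changed 2-fold were recovered, with 7 false calls. For gamma the shares were 14%, 72%, 90% and 98%, with 10 false calls. For alpha minus gamma they were 0%, 50%, 82% and 96%, with 3 false calls. These shares describe the simulated setting only. In the data, 71.1% of features were called for alpha and 72.6% for gamma, and array weights ran from 0.214 to 2.81. The number of arrays limits the precision: the median 95% interval reached 0.0962 to each side of a compound's log2 ratio and 0.136 to each side of the difference between compounds.

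The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Nor do they say whether the control RNA was shared between arrays, and the dose is not given. The alternatives tried were no background subtraction, the scanner software's ratio, median centring, scaling between arrays, no and stricter probe filters, no dye coefficient, a replicate block, dye-swap pairs averaged or as a random block, scanning session or slide as a block, array weights, another moderation, the mean over a gene's probes, the authors' value table, other thresholds, each compound fitted alone, and each array left out in turn.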

Results

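Gene expression was measured in Caco-2 cells, a human colorectal adenocarcinoma line that takes on features of small intestinal absorptive cells in culture. The cells received mixed micelles, the bile salt and lipid particles that carry fat-soluble compounds to the gut lining. For 24 h the micelles were enriched in alpha-tocopherol or in gamma-tocopherol, and micelles without added tocopherol served as control. Both compounds are forms of vitamin E, and gamma-tocopherol lacks 1 methyl group on the chromanol ring that alpha-tocopherol carries. There were 4 arrays per compound, each setting treated against control RNA directly. Median spot intensities before background correction ranged from 101.8 to 140.6 in the Cy3 channel and from 91.2 to 173.1 in the Cy5 channel. The share of spots well above background ranged from 37.8% to 58.7% in Cy3, and its lowest value was on the array labelled gamma replicate 4. That array also had the widest spread between spots of the same probe, with an SD of 0.0959 on the log2 scale against 0.0375 to 0.0453 on the other arrays.

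The largest rises with alpha-tocopherol micelles included genes of protein folding and metal binding, and the largest falls included genes of fat, bile acid and sterol handling. HSPA1A, an inducible cytosolic HSP70 chaperone, rose by 3.77 ± 0.13 on the log2 scale (SE, n = 4), which is 13.6-fold. HSPA6, another stress-induced HSP70, rose by 3.36 ± 0.12, the zinc-binding protein gene MT2A by 2.99 ± 0.17 and the HSP40 co-chaperone gene DNAJB1 by 2.31 ± 0.07. FABP6, the ileal bile acid binding protein, fell by 2.65 ± 0.03, and FABP1, the liver-type fatty acid binding protein, fell by 2.05 ± 0.03. SOAT2, which esterifies cholesterol in enterocytes, fell by 2.06 ± 0.08. These 7 genes had adjusted p-values from 8.8e-09 (FABP6) to 1.8e-06 (MT2A) in limma and, as the naming rule required, the same direction in all 4 arrays. HSPA1A has a near-identical copy, HSPA1B, and MT2A has close relatives, so their probes cannot assign the signal to a single gene.

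Among the other largest rises were the stress transcription factors JUN (2.08 ± 0.08) and ATF3 (2.07 ± 0.05), the endoplasmic reticulum co-chaperone DNAJB9 (2.23 ± 0.06) and the kinase gene PLK2 (2.30 ± 0.05). The orphan nuclear receptor NR4A3 changed by 2.17 ± 0.15, the Wnt antagonist DKK1 by 2.16 ± 0.29, EID3 by 2.13 ± 0.21 and the cAMP-responsive factor CREM by 2.29 ± 0.27. Of the 3 further CREM probes, 1 gave -0.03 and was not called. The other largest falls included MLXIPL, which encodes the glucose-responsive factor ChREBP (-2.35 ± 0.06), the aminotransferase gene AGXT2 (-2.17 ± 0.11) and the creatine synthesis gene GATM (-2.10 ± 0.15). MLXIPL had a further probe at -1.48 and another at 0.16, the only further probe of a named gene that was called in the opposite direction. PIGZ fell by 2.19 ± 0.04, the sialyltransferase gene ST6GAL1 by 2.09 ± 0.06, the glutathione transferase gene GSTA2 by 1.99 ± 0.09, and the calcium-binding protein gene S100G by 1.94 ± 0.04. LHPP fell by 1.90 ± 0.05 and the lactate dehydrogenase gene LDHD by 1.89 ± 0.18. As the naming rule required, all of these were called and had the same direction in all 4 arrays. Their adjusted p-values were at most 2.5e-04 (DKK1) in limma.

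In the whole set, 12702 of 17857 features (71.1%) were called for alpha-tocopherol in limma, of which 5940 rose and 6762 fell, and 690 changed at least 2-fold (362 rose and 328 fell). With median centring in place of loess, 697 rose and 226 fell, so that rises made up 75.5% of calls against 46.8%. Without the array labelled alpha replicate 4, 11764 features were called.

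The stress lists rose with alpha-tocopherol. Of 14 heat shock genes, 13 rose and 1 fell (median 1.19, adjusted p = 7.8e-06; adjusted p = 0.472 with an estimated correlation), with DNAJA1 at 1.53 ± 0.04 besides the genes above and the mitochondrial chaperonin HSPE1 as the member that fell (-0.50). Of 27 genes of the endoplasmic reticulum stress and ATF4 response, 23 rose, 2 fell and 2 did not pass (median 1.17, adjusted p = 2.0e-08; adjusted p = 0.427 with an estimated correlation). In this list CEBPB, a transcription factor, rose by 1.69 ± 0.03 and XBP1, a regulator of the unfolded protein response, rose by 1.23 ± 0.03. Of 23 immediate early genes, 21 rose, 1 fell and 1 did not pass (median 0.78, adjusted p = 8.5e-07; adjusted p = 0.427 with an estimated correlation), among them the phosphatase DUSP1 (1.64 ± 0.06), the matricellular protein CCN1 (2.06 ± 0.08) and PHLDA1 (0.78 ± 0.03), of whose 3 further probes 1 was not called (0.21). Of 21 NF-kB and inflammation genes, 17 rose, 2 fell and 2 did not pass (median 0.64, adjusted p = 6.3e-04; adjusted p = 0.523 with an estimated correlation). The chemokine CXCL2 rose by 1.54 ± 0.08 and the NF-kB inhibitor NFKBIA by 1.30 ± 0.06, with smaller rises of NFKB1 (0.53 ± 0.04) and TNFAIP3 (0.82 ± 0.07). Of 22 NRF2 targets and regulators, 14 rose, 4 fell and 4 did not pass (median 0.58, adjusted p = 0.00362; adjusted p = 0.523 with an estimated correlation). NFE2L2, which encodes NRF2, was at 1.46 ± 0.03 (n = 3 arrays, 1 value being missing) on its brightest probe and at -0.06 on a dim further probe that was not called. Sulfiredoxin (SRXN1) rose by 1.70 ± 0.05, the glutathione synthesis gene GCLC by 1.003 ± 0.04 and the cystine transporter SLC7A11 by 1.67 ± 0.08, while the quinone reductase NQO1 fell by 0.19 ± 0.03 and heme oxygenase HMOX1 fell by 0.22 ± 0.07, although not on every array before dye correction. Of 17 p53 and growth arrest genes, 14 rose and 3 fell (median 0.47, adjusted p = 0.00115; adjusted p = 0.427 with an estimated correlation), with the cytokine GDF15 at 2.02 ± 0.04, GADD45A at 0.89 ± 0.04 and TP53INP1 at -1.37 ± 0.05. Of 14 metallothionein and zinc transport genes, 10 rose, 2 fell and 2 did not pass (median 0.82, adjusted p = 0.0235; adjusted p = 0.551 with an estimated correlation), a call that also ended with the stricter probe filter. MT1H rose by 1.02 ± 0.10, and the zinc importers SLC39A4 (-0.58 ± 0.04) and SLC39A10 (-0.53 ± 0.05) fell.

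Lipid and sterol genes mostly fell with alpha-tocopherol. Of 20 cholesterol synthesis genes, 18 fell, 1 rose and 1 did not pass (median -0.72, adjusted p = 7.7e-05; adjusted p = 0.543 with an estimated correlation); as the topic of the study's paper, this list is not independent evidence of its direction. Lanosterol synthase (LSS) fell by 1.48 ± 0.04, farnesyl diphosphate synthase (FDPS) by 1.12 ± 0.08 and HMGCS1 by 0.65 ± 0.03. Of 16 sterol sensing and uptake genes, 6 rose and 10 fell (median -0.29, adjusted p = 0.424), a list of the same topic and not called. The ubiquitin ligase MYLIP rose by 0.60 ± 0.03 and the master regulator SREBF2 by 0.18 ± 0.03. By contrast, SREBF1 (-0.76 ± 0.07), the sterol sensor partners SCAP (-0.40 ± 0.03) and INSIG1 (-0.31 ± 0.08), the lysosomal lipase LIPA (-1.18 ± 0.05), the lipoprotein receptor SCARB1 (-0.97 ± 0.06) and the cholesterol importer NPC1L1 (-0.28 ± 0.05) fell. Of 21 lipid absorption and lipoprotein genes, 16 fell, 4 rose and 1 did not pass (median -0.37, adjusted p = 0.00249; adjusted p = 0.472 with an estimated correlation). The apolipoprotein genes APOC3 (-1.36 ± 0.04), APOA4 (-1.18 ± 0.03) and APOA1 (-0.31 ± 0.03) fell, and SAR1B, which is needed for chylomicron export, rose by 0.99 ± 0.03. Of 22 PPAR and fatty acid oxidation genes, 17 fell, 3 rose and 2 did not pass (median -0.48, adjusted p = 7.3e-04; adjusted p = 0.427 with an estimated correlation). They included ECI1 (-0.89 ± 0.03), the carnitine carrier SLC25A20 (-1.09 ± 0.05), ACADVL (-0.70 ± 0.03) and HADHA (-0.58 ± 0.03), whose dimmer further probe was at -0.05 and not called. Of 10 bile acid and FXR genes, 9 fell and 1 did not pass (median -0.49, adjusted p = 0.00115; adjusted p = 0.427 with an estimated correlation), with the basolateral bile acid exporter subunits SLC51A (-1.46 ± 0.08) and SLC51B (-1.13 ± 0.03) and the apical importer SLC10A2 (-0.67 ± 0.04). Of 14 fatty acid synthesis genes, 9 fell, 2 rose and 3 did not pass (median -0.41, adjusted p = 0.0549, and 0.0214 in session 2 alone). The citrate carrier SLC25A1 was at -1.01 ± 0.04, malic enzyme ME1 at 0.68 ± 0.04, ACSS2 at -1.23 ± 0.07 with a further probe at 0.05 that was not called, and the desaturase SCD at -1.29 ± 0.09 with further probes at -0.13 and -0.18 that were not called. Of 11 LXR and cholesterol efflux genes, 8 fell and 3 rose (median -0.31, adjusted p = 0.151), with the exporter ABCA1 at -1.13 ± 0.11 and the LXR-alpha gene NR1H3 at -0.95 ± 0.05. Of 8 vitamin E transport genes, 6 fell, 1 rose and 1 did not pass (median -0.30, adjusted p = 0.0877), with SEC14L1 at 0.95 ± 0.05, of which a dim further probe was at 0.11 and not called, and LRP1 at -0.32 ± 0.04.

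Genes of energy metabolism and antioxidant enzymes also fell. Of 31 genes of oxidative phosphorylation, 30 fell and 1 did not pass (median -0.45, adjusted p = 2.3e-08; adjusted p = 0.427 with an estimated correlation), such as the complex I genes NDUFV1 and NDUFA1 (both -0.79 ± 0.03), UQCRC1 (-0.73 ± 0.03) and COX7B (-0.63 ± 0.03). Of 26 hypoxia and glycolysis genes, 21 fell, 3 rose and 2 did not pass (median -0.43, adjusted p = 2.7e-04; adjusted p = 0.427 with an estimated correlation), with BNIP3 at -1.36 ± 0.03, PDK1 at -0.90 ± 0.04, PGK1 at -0.87 ± 0.03 and LDHA at -0.71 ± 0.03. Of 18 antioxidant enzymes, 16 fell and 2 rose (median -0.36, adjusted p = 5.2e-04; adjusted p = 0.427 with an estimated correlation). The peroxiredoxins PRDX2 (-0.79 ± 0.03) and PRDX3 (-0.73 ± 0.03), catalase CAT (-0.69 ± 0.04) and PON3 (-0.96 ± 0.03) fell. The 25 xenobiotic metabolism genes were not called as a list in camera, and 6 rose, 12 fell and 7 did not pass (median -0.08, adjusted p = 0.288). Fry called them (fry adjusted p = 0.001201), as it did 51 of the 81 list tests. These included other lists that camera did not call for alpha-tocopherol, such as LXR (fry adjusted p = 0.00167), interferon (0.00549) and enterocyte markers (1.8e-04). The xenobiotic median was 0.10 with median centring and -0.22 in session 1 alone. Without the array labelled alpha replicate 4 it was -0.20 with 14 falls. Camera called the xenobiotic list in none of these fits. The aryl hydrocarbon receptor AHR was at 1.105 ± 0.04, UGT2B7 at -1.44 ± 0.05, GSTA1 at -1.82 ± 0.05, GSTA5 at -1.89 ± 0.06 and the drug-metabolizing CYP3A4 at 0.08 ± 0.06, not called. The GSTA family members are too alike to be told apart by these probes.

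None of the lists of cell state was called in camera with alpha-tocopherol. Of 31 cell cycle genes, 7 rose, 5 fell and 19 did not pass, with a median of -0.01 (0.12 with median centring) and a mean of 0.01 (adjusted p = 0.960). CDC6 and CCNE1 were both at 0.42 ± 0.04, CCNB2 at -0.25 ± 0.03 with a further probe at -0.05 that was not called, and TYMS at -0.23 ± 0.04. Of 21 enterocyte differentiation markers, 14 fell, 4 rose and 3 did not pass (median -0.32, adjusted p = 0.0549), with villin (VIL1) at -0.98 ± 0.04, the peptidase MEP1A at -0.85 ± 0.03, sucrase-isomaltase (SI) at -0.66 ± 0.04 and CEACAM5 at 1.06 ± 0.06. This list was called with scanning session as a block, in session 1 (adjusted p = 0.0429) and without the array labelled alpha replicate 4 (adjusted p = 0.0304; adjusted p = 0.469 with an estimated correlation). Of 24 tight junction and adhesion genes, 12 rose, 8 fell and 4 did not pass (median 0.10, adjusted p = 0.266), with the scaffold TJP1 at 1.77 ± 0.08, claudin CLDN1 at 0.98 ± 0.05, integrin ITGA6 at 0.72 ± 0.06 and cingulin (CGN) at -0.59 ± 0.04. Of 18 TGF-beta and Wnt targets, 6 rose, 5 fell and 7 did not pass (median 0.03, adjusted p = 0.811), with ID2 at -1.09 ± 0.04, ID3 at -0.42 ± 0.03, ZNRF3 at -0.27 ± 0.03 with a further probe at -0.10 that was not called, and AXIN2 at 0.55 ± 0.06. Of 19 interferon genes, 3 rose, 8 fell and 8 did not pass (median -0.09, adjusted p = 0.126), with IFIT1 at -1.34 ± 0.15, IRF7 at -0.72 ± 0.06, ISG15 at -0.65 ± 0.04 and IFIH1 at -0.39 ± 0.04, and the list was called in session 1 alone (adjusted p = 0.0430). Of 9 secretory lineage markers, 3 rose, 1 fell and 5 did not pass (median 0.04, adjusted p = 0.586), with AGR2 at 1.43 ± 0.06, TFF3 at -0.92 ± 0.04 and MUC13 at 0.26 ± 0.04. Of 9 crypt stem cell markers, 1 rose, 4 fell and 4 did not pass (median -0.03, adjusted p = 0.430), with ASCL2 at -0.92 ± 0.03, PROM1 at -0.33 ± 0.03, BMI1 at -0.40 ± 0.03 with a further probe at -0.06 that was not called, and RGMB at 0.50 ± 0.06. Of 9 stromal and immune markers, 2 rose, 5 fell and 2 did not pass (median -0.25, adjusted p = 0.345). FN1 was at 0.41 ± 0.04, with a further probe at 0.41 and another at 0.38 that was not called. SPARC was at -0.41 ± 0.04, CD68 at -0.27 ± 0.03 and COL6A1 at -0.65 ± 0.05, whose dim further probe was at -0.01 and not called.

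In all, camera called 14 of 27 lists for alpha-tocopherol. Each of these had a median of the same direction in all 4 arrays, in both scanning sessions and without the array labelled alpha replicate 4. No list call of any comparison (0 of 81) held with an estimated correlation between genes. That loss does not measure the correlation alone. Without the array labelled alpha replicate 4, the tight junction list had an estimated correlation of -0.024, below the preset 0.01. Its unadjusted camera p for alpha minus gamma still went from 5.7e-09 to 0.0035. Adjusted over the list alone, the counts above were the same except for 6 rises in the cell cycle list and 7 falls in the interferon list. With scanning session as a block 12800 features were called for alpha-tocopherol, against 13556 in session 1 alone and 6575 in session 2 alone. Slide 2 is session 2, and slide 1 alone left no residual degrees of freedom.

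**Figure D1:**
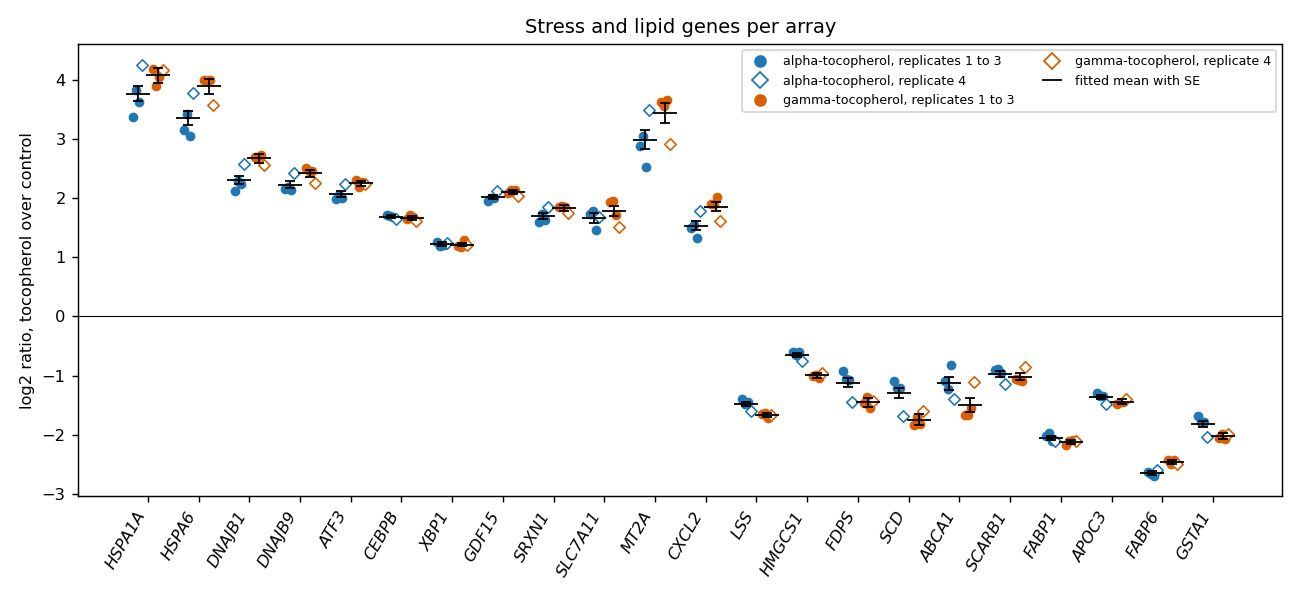
Dye-corrected log2 ratios of tocopherol over control (vertical axis) for 22 named stress and lipid genes, 1 point per array, alpha-tocopherol in blue and gamma-tocopherol in orange, with open diamonds for the arrays numbered 4 and bars for the fitted mean with its SE. HSPA1A stood at 3.77 and 4.08 and FABP6 at -2.65 and -2.46 for alpha- and gamma-tocopherol.

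Gamma-tocopherol micelles raised and lowered the same leading genes. HSPA1A rose by 4.08 ± 0.13 on the log2 scale (SE, n = 4), or 16.9-fold, HSPA6 by 3.89 ± 0.12, MT2A by 3.44 ± 0.17 and DNAJB1 by 2.67 ± 0.07. FABP6 fell by 2.46 ± 0.03, ST6GAL1 by 2.31 ± 0.06, SOAT2 by 2.13 ± 0.08 and FABP1 by 2.12 ± 0.03. ANXA1, a phospholipid-binding protein, rose by 2.32 ± 0.12 and CCN1 by 2.36 ± 0.08. These 10 genes had adjusted p-values from 1.0e-08 (FABP6) to 9.1e-07 (ANXA1) in limma and, as the naming rule required, the same direction in all 4 arrays.

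The other largest rises with gamma-tocopherol were DKK1 (2.62 ± 0.29), PLK2 (2.46 ± 0.05), EID3 (2.45 ± 0.21), DNAJB9 (2.42 ± 0.06) and JUN (2.33 ± 0.08). The control channel of DKK1, EID3 and CREM was well above background on 3 of 4 gamma-tocopherol arrays. The other largest falls were MLXIPL (-2.27 ± 0.06, with a further probe at 0.18), AGXT2 (-2.27 ± 0.11), S100G (-2.13 ± 0.04), GSTA5 (-2.12 ± 0.06), the methyltransferase TMT1A (-2.11 ± 0.09), the antimicrobial peptide gene DEFB1 (-2.06 ± 0.06), GATM (-2.05 ± 0.15) and GSTA1 (-2.02 ± 0.05). All had adjusted p-values of at most 7.3e-05 (DKK1) in limma and, as the naming rule required, the same direction in all 4 arrays. In the whole set, 12960 of 17857 features (72.6%) were called, of which 6158 rose and 6802 fell, and 857 changed at least 2-fold (495 rose and 362 fell). With median centring 1524 were called.

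Stress lists rose with gamma-tocopherol. Of the heat shock genes, 13 rose and 1 fell (median 1.47, adjusted p = 7.8e-06; adjusted p = 0.472 with an estimated correlation). Of the endoplasmic reticulum stress and ATF4 genes, 22 rose, 1 fell and 4 did not pass (median 1.22, adjusted p = 1.6e-08; adjusted p = 0.427 with an estimated correlation), with ATF3 at 2.25 ± 0.05, CEBPB at 1.66 ± 0.03 and XBP1 at 1.22 ± 0.03. Of the immediate early genes, 21 rose, 1 fell and 1 did not pass (median 0.73, adjusted p = 1.6e-06; adjusted p = 0.427 with an estimated correlation), with DUSP1 at 1.84 ± 0.06. Of the NF-kB genes, 17 rose, 2 fell and 2 did not pass (median 1.004, adjusted p = 3.4e-04; adjusted p = 0.523 with an estimated correlation), with CXCL2 at 1.86 ± 0.08 and TNFAIP3 at 1.06 ± 0.07. Of the NRF2 genes, 14 rose, 2 fell and 6 did not pass (median 0.65, adjusted p = 0.00168; adjusted p = 0.523 with an estimated correlation), with SRXN1 at 1.83 ± 0.05, SLC7A11 at 1.78 ± 0.08, NQO1 at -0.20 ± 0.03 and HMOX1, not called, at -0.02 ± 0.07. Of the p53 and growth arrest genes, 14 rose and 3 fell (median 0.51, adjusted p = 0.00120; adjusted p = 0.427 with an estimated correlation), with GDF15 at 2.10 ± 0.04. Of the metallothionein and zinc transport genes, 12 rose and 2 fell (median 1.12, adjusted p = 0.00808; adjusted p = 0.541 with an estimated correlation), a call that also ended with the stricter probe filter. Tight junction and adhesion genes were called with gamma-tocopherol, with 14 rises, 4 falls and 6 that did not pass (median 0.16, adjusted p = 0.0374; adjusted p = 0.588 with an estimated correlation), but not with the scanner software's own ratio. TJP1 rose by 2.11 ± 0.08 and CLDN1 by 1.12 ± 0.05.

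Lipid and energy lists fell with gamma-tocopherol. Of the cholesterol synthesis genes, not independent evidence for the reason given, 18 fell, 0 rose and 2 did not pass (median -1.05, adjusted p = 7.6e-06; adjusted p = 0.533 with an estimated correlation), with LSS at -1.67 ± 0.04, FDPS at -1.45 ± 0.08 and HMGCS1 at -0.998 ± 0.03. Of the fatty acid synthesis genes, 10 fell, 1 rose and 3 did not pass (median -0.39, adjusted p = 0.0156; adjusted p = 0.523 with an estimated correlation), with SCD at -1.74 ± 0.09 (further probes at -0.70 and -0.35) and ACSS2 at -1.46 ± 0.07 (a further probe at -0.15). Of the lipid absorption genes, 15 fell, 4 rose and 2 did not pass (median -0.31, adjusted p = 0.00366; adjusted p = 0.472 with an estimated correlation), with APOC3 at -1.44 ± 0.04. Of the PPAR and fatty acid oxidation genes, 16 fell, 2 rose and 4 did not pass (median -0.48, adjusted p = 0.00120; adjusted p = 0.453 with an estimated correlation), with ECI1 at -0.87 ± 0.03. Of the bile acid and FXR genes, 9 fell and 1 rose (median -0.45, adjusted p = 0.00321; adjusted p = 0.427 with an estimated correlation), with SLC51A at -1.05 ± 0.08. Of the oxidative phosphorylation genes, 30 fell and 1 rose (median -0.44, adjusted p = 2.4e-08; adjusted p = 0.427 with an estimated correlation), with NDUFV1 at -0.83 ± 0.03. Of the hypoxia and glycolysis genes, 20 fell, 2 rose and 4 did not pass (median -0.50, adjusted p = 2.2e-04; adjusted p = 0.427 with an estimated correlation), with BNIP3 at -1.45 ± 0.03. Of the antioxidant enzymes, 15 fell, 2 rose and 1 did not pass (median -0.33, adjusted p = 0.00115; adjusted p = 0.427 with an estimated correlation), with catalase at -0.85 ± 0.04.

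Camera called none of the remaining lists for gamma-tocopherol. Fry called all of them, with fry adjusted p from 1.8e-04 (crypt stem cell markers) to 0.0376 (interferon). Of the sterol sensing and uptake genes, again not independent evidence, 5 rose, 10 fell and 1 did not pass (median -0.36, adjusted p = 0.177), with SREBF2 at 0.19 ± 0.03, SREBF1 at -0.68 ± 0.07, INSIG1 at -0.68 ± 0.08, NPC1L1 at -0.39 ± 0.05 and SCARB1 at -1.02 ± 0.06. SCARB1 had a further probe at -0.42 and another at -0.15 that was not called. Of the LXR genes, 3 rose, 7 fell and 1 did not pass (median -0.36, adjusted p = 0.1696), with ABCA1 at -1.50 ± 0.11. Of the vitamin E transport genes, 1 rose, 6 fell and 1 did not pass (median -0.34, adjusted p = 0.0699). Of the xenobiotic metabolism genes, 11 rose, 9 fell and 5 did not pass; the median was 0.04 (-0.01 with the scanner software's ratio), the mean was -0.16 and camera's direction was up (adjusted p = 0.979), with AHR at 1.06 ± 0.04, UGT2B7 at -1.56 ± 0.05 and CYP3A4 at 0.38 ± 0.06. Of the cell cycle genes, 4 rose, 16 fell and 11 did not pass (median -0.12, adjusted p = 0.0909), with TYMS at -0.46 ± 0.04, and the list was called in session 1 (adjusted p = 0.0460) and without the array labelled alpha replicate 4 (adjusted p = 0.0407; adjusted p = 0.482 with an estimated correlation). Of the enterocyte markers, 6 rose, 13 fell and 2 did not pass (median -0.22, adjusted p = 0.152), with SI at -0.87 ± 0.04 and CEACAM5 at 1.20 ± 0.06. Of the TGF-beta and Wnt targets, 9 rose, 7 fell and 2 did not pass (median 0.06, and -0.03 with median centring; adjusted p = 0.871). Of the interferon genes, 4 rose, 10 fell and 5 did not pass (median -0.12, adjusted p = 0.348). Of the secretory markers, 4 rose, 2 fell and 3 did not pass (median 0.08, adjusted p = 0.405), with AGR2 at 1.63 ± 0.06 and NEUROG3 at 0.26 ± 0.06, against -0.08 ± 0.06 with alpha-tocopherol, where it was not called. Of the crypt stem cell markers, 2 rose, 4 fell and 3 did not pass; the median was 0.00 (-0.29 with the scanner software's ratio), the mean was -0.15 and the direction was down (adjusted p = 0.436). Of the stromal and immune markers, 3 rose, 5 fell and 1 did not pass (median -0.23, adjusted p = 0.543).

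All 16 lists that camera called had medians of the same direction in all 4 gamma-tocopherol arrays and in both scanning sessions. Adjusted over the list alone, the counts were the same except for 11 falls in the sterol sensing list, 2 rises in the fatty acid synthesis list, 3 rises in the hypoxia list and 14 falls among the enterocyte markers. With scanning session as a block 13057 features were called for gamma-tocopherol, against 13839 in session 1 alone and 6601 in session 2 alone.

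**Figure D2:**
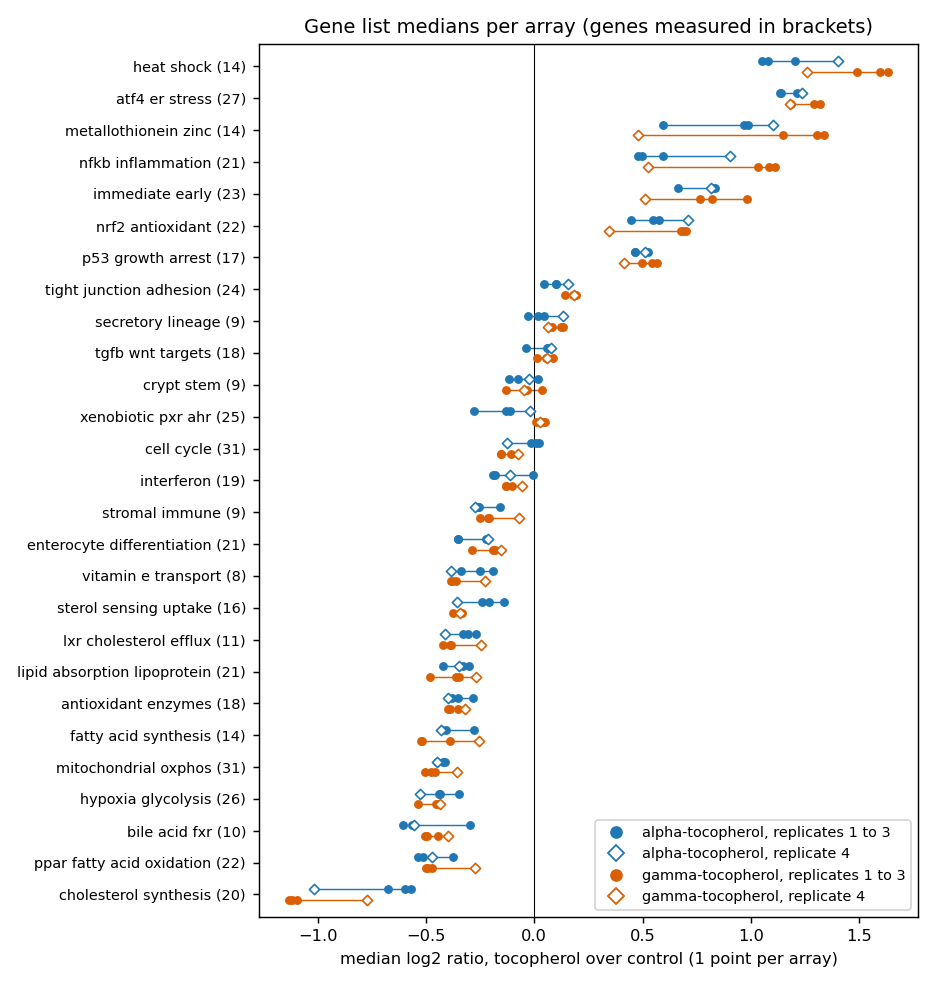
Median log2 ratio of tocopherol over control (horizontal axis, dye effect removed) of the 27 gene lists, with 1 point per array, a line spanning the 4 arrays of a compound and open diamonds for the arrays numbered 4. The cholesterol synthesis list lay lowest, with fitted medians of -0.72 (alpha) and -1.05 (gamma), and the heat shock list highest, at 1.19 and 1.47. For alpha the endoplasmic reticulum stress and ATF4 list was close, at 1.17. It was the higher of both without the array labelled alpha replicate 4 (1.12 against 1.07).

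**Figure D3:**
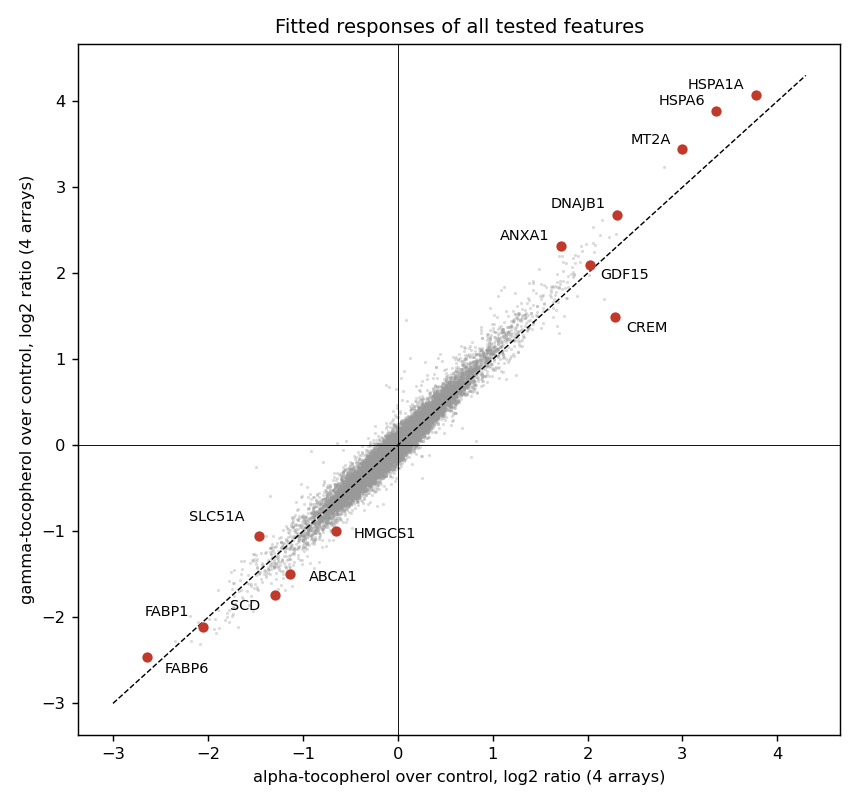
Fitted log2 ratios of alpha-tocopherol (horizontal axis) and gamma-tocopherol (vertical axis) over control for 17857 features in grey, with named genes in red and a dashed line of equal response. The responses had a Pearson correlation of 0.975 across features.

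The responses to both compounds resembled each other across genes. The correlation across the 17857 features, which are not independent replicates, was 0.975 (Pearson) and 0.964 (Spearman), with a covariance of 0.201, and 91.1% had the same sign. Unchanged genes were simulated 20 times. With a control RNA shared within pairs of an alpha- and a gamma-tocopherol array, the mean correlation was 0.507 and the covariance 0.00170. With separate control RNA the correlation was near 0 (-9.4e-04). A control common to all arrays was not simulated. Alpha-tocopherol in session 1 set against gamma-tocopherol in session 2 gave 0.934 (covariance 0.184), and the reverse pairing gave 0.968 (0.212). Rises in both numbered 5342 (2048 for independent lists of these sizes) and falls in both 6057 (2576), and 7 features were called in opposite directions. The SD of the gamma-tocopherol log2 ratios was 1.07 times that of the alpha-tocopherol ratios.

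The direct comparison of alpha- with gamma-tocopherol, which differ by 1 methyl group, called no single gene when all 8 arrays counted equally. With array weights it called 2902. The weights were estimated from the same arrays under their labels, so arrays that departed from their group counted least. The lowest were 0.214 for gamma replicate 4 and 0.35 for alpha replicate 4, and the 2902 are not separate support for a difference. Camera set 11 lists apart, of which 0 held with an estimated correlation and fry called 0. In camera the cholesterol synthesis genes lay higher with alpha-tocopherol, having fallen less, and the heat shock genes and metallothioneins lay lower, having risen less. HMGCS1, an early enzyme of cholesterol synthesis, fell by 0.65 with alpha- and by 0.998 with gamma-tocopherol, a difference of 0.34 (95% interval 0.23 to 0.46). CDK7, a kinase of transcription and the cell cycle, rose by 0.68 and 0.94, a difference of -0.26 (-0.36 to -0.16). Neither passed the threshold in limma (adjusted p = 0.377 for both). All 4 arrays of each compound lay on their own side, but choosing genes by the smallest p favours this, so it adds no support.

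Of 17857 features, 0 were called in limma for alpha minus gamma with equal weights, and 2216 had an unadjusted p under 0.05. The other genes with the smallest p were LMNB2 (0.23, 0.13 to 0.33), ZNF777 (0.23, 0.13 to 0.34), RPS6KC1 (-0.22, -0.32 to -0.12) and DAPK3 (-0.22, -0.33 to -0.12), all at an adjusted p of 0.377. A further ZNF777 probe lay the other way, at 0.26 with alpha- and 0.35 with gamma-tocopherol. The intervals of other named genes show how far the compounds were matched on the probe that stood for each gene. FABP1 differed by 0.07 (-0.04 to 0.17), XBP1 by 0.01 (-0.09 to 0.11), APOA4 by 0.02 (-0.09 to 0.13) and LDHA by 0.01 (-0.08 to 0.11). Further probes, for alpha- and then gamma-tocopherol, were at 1.11 and 1.22 for XBP1 and at -0.77 and -0.57 for APOA4. Those of LDHA were at -0.76 and -0.70, and at -0.70 and -0.49. The intervals of these genes therefore cannot be extended to their other probes. Wider intervals were found for ABCA1 (0.37, -0.01 to 0.74), MT2A (-0.45, -0.996 to 0.10), HSPA1A (-0.31, -0.72 to 0.11) and CREM (0.80, -0.09 to 1.70). Differences with intervals off 0 but past no threshold (adjusted p = 0.377) included SCD (0.45, 0.15 to 0.75), INSIG1 (0.37, 0.11 to 0.64), ANXA1 (-0.61, -0.99 to -0.22), SLC51A (-0.41, -0.69 to -0.14) and CYP3A4 (-0.30, -0.50 to -0.11). The same held for HSPA6 (-0.53, -0.93 to -0.13) and DNAJB1 (-0.36, -0.59 to -0.14). Without the array labelled alpha replicate 4, the intervals of MT2A (-1.16 to -0.14) and HSPA1A (-0.75 to -0.26) lay off 0. That of CREM did not (-0.23 to 2.02). None of MT2A, HSPA1A and CREM was then called in limma (adjusted p = 0.154, 0.0573 and 0.349). Of the other largest rises with alpha-tocopherol, HSPA6 (-0.70, adjusted p = 0.0429), DNAJB1 (-0.47, 0.0161), JUN (-0.38, 0.0261) and ATF3 (-0.25, 0.0304) were then called. PLK2, DNAJB9, NR4A3, DKK1 and EID3 were not. Of its largest falls, FABP6 (-0.21, 0.0490), ST6GAL1 (0.31, 0.0403) and S100G (0.24, 0.0457) were called and the others were not.

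The count depended on the weight of single arrays. Array weights on all 8 arrays, estimated under the same labels, gave 2902 features. Of these, 1028 were higher with alpha- and 1874 higher with gamma-tocopherol. Session 1 alone gave 1461, from only the arrays numbered 1 and 2 of each compound, which left little to estimate each gene's spread from. Both alpha-tocopherol arrays and gamma replicate 2 were then on slide 1 and gamma replicate 1 on slide 3, so slide and compound partly overlapped. Without the array labelled alpha replicate 4, 601 features were called, of which 182 were higher with alpha- and 419 higher with gamma-tocopherol, and 25 differed at least 1.5-fold. Among the named genes, ANXA1 then differed by -0.79 (-1.001 to -0.59, adjusted p = 0.0174 in limma), SCD by 0.60 (0.50 to 0.70, adjusted p = 0.00738), SLC51A by -0.55 (-0.64 to -0.47, adjusted p = 0.00738), INSIG1 by 0.50 (0.34 to 0.65, adjusted p = 0.0236) and HMGCS1 by 0.39 (adjusted p = 0.0143). In each of these 5 genes the dye-corrected values of the other 3 alpha-tocopherol arrays all lay on the same side of the 4 gamma-tocopherol arrays. Being called on these same arrays makes that separation likely, so it adds no support.

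**Figure D4:**
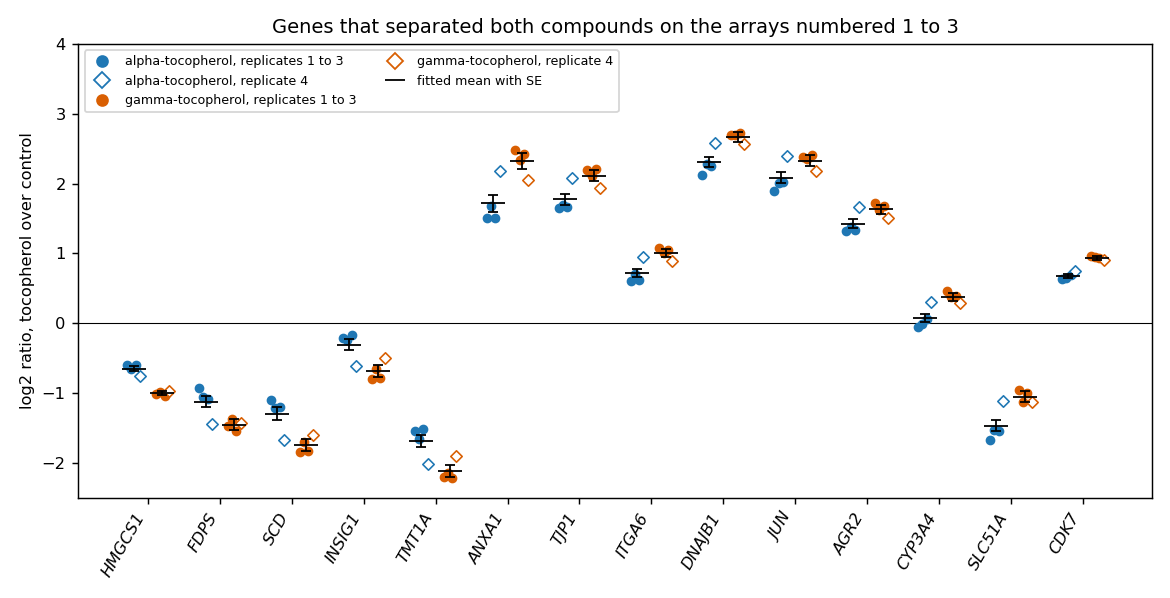
Dye-corrected log2 ratios of tocopherol over control (vertical axis) for 14 named genes, picked after their values were seen, with 1 point per array and bars for the fitted mean with its SE. The open blue diamond of the array labelled alpha replicate 4 lies nearer the orange gamma-tocopherol points than the other blue points do, as for SCD at -1.68 against -1.09 to -1.21 on the other alpha-tocopherol arrays.

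Camera called 11 lists for alpha minus gamma, none of which fry called. Values below are the median log2 difference, followed by those within sessions 1 and 2. Higher with alpha-tocopherol was cholesterol synthesis (0.19, then 0.40 and 0.17; adjusted p = 3.1e-09; adjusted p = 0.472 with an estimated correlation). So were fatty acid synthesis (0.13, then 0.21 and 0.07; adjusted p = 0.00403; adjusted p = 0.496 with an estimated correlation) and sterol sensing and uptake (0.07, then 0.08 and 0.06; adjusted p = 0.0182; adjusted p = 0.543 with an estimated correlation). So were the cell cycle list (0.10, then 0.12 and 0.07; adjusted p = 1.6e-08; adjusted p = 0.472 with an estimated correlation) and the hypoxia and glycolysis list (0.03, then 0.07 and 0.02; adjusted p = 0.0299; adjusted p = 0.530 with an estimated correlation). Higher with gamma-tocopherol was heat shock (-0.20, then -0.34 and -0.09; adjusted p = 2.5e-04; adjusted p = 0.496 with an estimated correlation). So were metallothionein and zinc transport (-0.24, then -0.43 and -0.08; adjusted p = 0.0198; adjusted p = 0.567 with an estimated correlation) and NF-kB (-0.05, then -0.23 and -0.03; adjusted p = 0.0467; adjusted p = 0.588 with an estimated correlation). So was tight junction and adhesion (-0.09, then -0.17 and -0.07, but 0.06 with median centring; adjusted p = 4.8e-06; adjusted p = 0.496 with an estimated correlation). The same held for endoplasmic reticulum stress and ATF4 (-0.08, then -0.09 and -0.04, but 0.15 with median centring; adjusted p = 0.0304; adjusted p = 0.543 with an estimated correlation) and xenobiotic metabolism (-0.09, then -0.12 and -0.10, but 0.06 with median centring; adjusted p = 0.0173; adjusted p = 0.472 with an estimated correlation). The cholesterol and sterol lists are again not independent evidence. Session 1 called all 11 and session 2 called 5. Lists not called over all arrays but called within 1 session were LXR, NRF2, vitamin E, immediate early, interferon and oxidative phosphorylation in session 1 (adjusted p = 0.0246, 0.00521, 0.0460, 0.0459, 0.0228 and 0.0164) and the stromal list in session 2 (0.0338). Without the array labelled alpha replicate 4, fry called cholesterol synthesis (median 0.33, fry adjusted p = 0.00126), cell cycle (0.14, 0.00122), heat shock (-0.31, 4.4e-04) and tight junction and adhesion (-0.14, 4.7e-05) among others, but neither NF-kB (-0.15, 0.244) nor metallothionein and zinc transport (-0.30, 0.193). None of these 6 lists was called in camera with an estimated correlation (adjusted p = 0.345, 0.218, 0.163, 0.163, 0.526 and 0.495 in the order given).

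No member of any list was called over all genes in this comparison with all 8 arrays. Without the array labelled alpha replicate 4, 10 of 20 cholesterol synthesis genes and 5 of 16 sterol sensing genes were called higher with alpha-tocopherol, and 5 of 14 heat shock and 6 of 24 tight junction genes higher with gamma-tocopherol. Adjusted over the list alone, the cholesterol synthesis count was then 15 and the heat shock count 8. Adjusted over the list alone with all 8 arrays, 12 cholesterol synthesis genes and 4 sterol sensing genes were higher with alpha-tocopherol, as were 1 immediate early gene and 1 TGF-beta or Wnt target. Higher with gamma-tocopherol on the same basis were 2 heat shock genes, 2 bile acid genes, 1 sterol sensing gene and 1 secretory marker. The other 16 lists were not called. Their medians were -0.07 for NRF2 (adjusted p = 0.0877), -0.07 for bile acid and FXR (0.0877), -0.07 for interferon (0.0620), -0.07 for enterocyte markers (0.0699), -0.04 for PPAR (0.515), -0.04 for p53 (0.246), -0.04 for immediate early genes (0.340) and -0.03 for antioxidant enzymes (0.950). They were -0.02 for secretory (0.238), -0.02 for stromal and immune markers (0.162), -0.02 for TGF-beta and Wnt targets (0.849, direction up), -0.01 for LXR (0.249, mean 0.06 and direction up), 0.01 for crypt stem cell markers (0.515), 0.02 for vitamin E transport (0.326) and 0.03 for oxidative phosphorylation (0.151). For lipid absorption the median was 0.02, the mean -0.01 and the direction up (0.718). With median centring, all 16 of these medians were above 0. Without the array labelled alpha replicate 4, camera also called NRF2 (adjusted p = 0.0468; adjusted p = 0.469 with an estimated correlation) and the enterocyte markers (adjusted p = 0.0410; adjusted p = 0.472 with an estimated correlation).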

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

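Among the tests in this part, those for a wrong label, a swap and the session or slide of alpha replicate 4, for dye, normalization and shared control RNA, and for dim channel and offset together were chosen only after the result was seen. In 4 arrays, a value was flagged when its gap to the nearest other array was large against the range of all 4, and chance flags about 1 in 20 groups in this way. Of all features, 5.29% were flagged for alpha-tocopherol and 6.01% for gamma-tocopherol. The flags were unevenly spread, with 703 of 1063 gamma-tocopherol flags on replicate 4, and with 377 and 327 of 939 alpha-tocopherol flags on replicates 4 and 3. All values are dye-corrected log2 ratios.

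The array labelled alpha-tocopherol replicate 4 was far from the other 3 for DKK1 (3.04 against 1.79 to 1.93), TJP1 (2.08 against 1.65 to 1.70), SI (-0.75 against -0.64 to -0.63) and INSIG1 (-0.62 against -0.24 to -0.17). Alpha replicate 3 was apart for MLXIPL (-2.17 against -2.41), SOAT2 (-1.88 against -2.14 to -2.11), SLC25A20 (-0.92 against -1.15 to -1.12), MT1H (0.79 against 1.08 to 1.12) and SREBF2 (0.24 against 0.16 to 0.17). So were its medians of the fatty acid synthesis list (-0.28 against -0.43 to -0.41) and the immediate early list (0.66 against 0.82 to 0.84). Alpha replicate 1 was apart for RGMB (0.65 against 0.43 to 0.46) and for the median of the TGF-beta and Wnt targets (-0.0366 against 0.06 to 0.08).

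The array labelled gamma-tocopherol replicate 4 was apart for HSPA6 (3.58 against 3.98 to 4.00), MT2A (2.92 against 3.56 to 3.66), DKK1 (1.55 against 2.94 to 3.02), SCARB1 (-0.85 against -1.09 to -1.06) and NFKBIA (1.12 against 1.41 to 1.42). It was also apart for COX7B (-0.63 against -0.69 to -0.68), COL6A1 (-0.44 against -0.71 to -0.68) and SREBF1 (-0.38 against -0.82 to -0.75), each time with the smaller change. Its list medians were smaller for cholesterol synthesis (-0.77 against -1.13 to -1.10), PPAR and fatty acid oxidation (-0.27 against -0.50 to -0.47), NRF2 (0.35 against 0.68 to 0.70), vitamin E transport (-0.23 against -0.39 to -0.36) and NF-kB (0.53 against 1.04 to 1.11). Gamma replicate 3 was apart for TYMS (-0.56 against -0.43 to -0.42), gamma replicate 2 for SREBF2 (0.26 against 0.16 to 0.17) and gamma replicate 1 for the hypoxia and glycolysis median (-0.54 against -0.45 to -0.44).

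Camera called a difference between the compounds for 11 lists, of which 0 held with an estimated correlation between genes and 0 were called by fry. The medians were 0.19 for cholesterol synthesis, 0.13 for fatty acid synthesis, 0.10 for cell cycle, 0.0655 for sterol sensing and uptake and 0.0318 for hypoxia and glycolysis. On the side of gamma-tocopherol they were -0.24 for metallothionein and zinc transport, -0.20 for heat shock, -0.0901 for tight junction and adhesion, -0.0874 for xenobiotic metabolism, -0.0812 for endoplasmic reticulum stress and ATF4 and -0.0541 for NF-kB.

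The array labelled alpha-tocopherol replicate 4 lay near the gamma-tocopherol arrays. On a scale with 0 at the mean of the other alpha-tocopherol arrays and 1 at that of the gamma-tocopherol arrays, over 500 genes chosen without the array in question, it lay at 0.965, with 97.4% of genes nearer gamma-tocopherol, which is what a mislabelled sample would give. Scanning session or slide was argued against by alpha replicate 3, of the same session and slide, at 0.0704, a larger response by a position of 0.954 over the 72 genes that alpha-tocopherol changed more, and a swap with gamma replicates 1 to 3 by their positions of 0.948, 1.06 and 0.949. Gamma replicate 4 lay at 0.425, and with the size of its response left free at 0.686 ± 0.069 (bootstrap SE over the 500 genes), near neither compound, but at 0.941 ± 0.115 with the scanner software's ratio, where gamma replicate 2 lay at 0.615 and alpha replicates 1 to 3 at 0.0723 to 0.398, so that a swap with it cannot be told. A wrong label therefore stays open, as does a biological difference of that sample, which was not tested.

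Both compounds gave wide responses that were nearly alike. Dye bias as the whole cause was argued against by a correlation of at least 0.768 between arrays of different compound and opposite dye orientation. For the profile across genes, normalization was argued against by the scanner software's own ratio. Its alpha-tocopherol responses had a correlation of 0.916 to those reported, although that ratio is dye-normalized too. A correlation cannot decide on the width of the responses. Median centring gave only 923 calls for alpha- and 1524 for gamma-tocopherol, so the number called depended on normalization. The correlation of both responses was then still 0.958. Chance values of a control RNA shared within pairs of arrays gave a simulated covariance of 0.00170 against 0.201. A control common to all arrays was not simulated. A shared control RNA that itself differed cannot be told apart from a like response. The labels do not say which control RNA was used, and the correlation across sessions was 0.934. A like biological response to both compounds also stays open.

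The array labelled gamma-tocopherol replicate 4 gave smaller changes than the other 3 gamma-tocopherol arrays, with a slope of 0.659 against them. A dim channel alone was argued against, since the slope rose by 0.542 from the dimmest to the brightest of 4 groups of genes but was still 0.843 in the brightest. The offset added in the background correction was argued against as the only cause, as the slope with the scanner software's ratio, which adds none, was 0.849. Both together went with the slopes of that ratio, 0.629 in the dimmest and 0.971 in the brightest group. No biological explanation was tested.

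For each compound, reversing the sign of arrays gave 8 splits, too few for a share under 0.05. The real split was 1 of 8 with as many genes for alpha-tocopherol (12702, highest other split 7) and 1 of 8 for gamma-tocopherol (12960, highest other 8). For lists, 5 of 8 splits gave as many for alpha-tocopherol (14, highest other 16) and 3 of 8 for gamma-tocopherol (16, highest other 18). For alpha minus gamma, 1 of the 35 splits equals the dye orientation and could not be fitted. With a real count of 0 genes, all 34 splits that could be fitted gave as many by construction, which decides nothing. For lists, 7 of the 34 gave as many lists as the real 11 (highest other 16), and chance was not excluded. The highest gene count, 97, came from the split that exchanges gamma replicate 4 with alpha replicate 4. That split was singled out after its count was seen, so nothing is concluded from it about the labels. Without alpha replicate 4, 1 of 34 splits, the real one, gave as many as 601 genes (highest other 8). That share does not allow for the choice of the array, which was made after the result was seen, so chance was not excluded. For its 13 lists, 4 of 34 splits gave as many (highest other 16), and chance was not excluded.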

How the results depend on the processing

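Leaving out both arrays numbered 4 together, fitting each scanning session alone, and session or slide as a block for lists and overlap were chosen after seeing the data; other alternatives were planned. Unless a change is named here, counts stayed within 1.5 times those reported. Median centring gave 923 genes for alpha- and 1524 for gamma-tocopherol, at a median residual SD of 0.449 against 0.0852 with loess, and turned the difference of the endoplasmic reticulum stress and ATF4 list to 0.15. For alpha minus gamma, array weights gave 2902 genes (the lowest weights were 0.214 for gamma replicate 4 and 0.3499 for alpha replicate 4). Leave-one-out gave 0 to 601 genes, the highest without alpha replicate 4. Without both arrays numbered 4 there were 1902, and GATM turned to 0.24. Session 1 alone gave 1461 genes and 17 lists for alpha minus gamma; session 2 alone gave 6 such lists and 6575 and 6601 genes for alpha- and gamma-tocopherol. The cause was not tested. At least 1.5-fold changes numbered 2679 and 3028, fewer by construction. With an estimated correlation 0 lists were called, and fry called 0 lists for alpha minus gamma. Leave-one-out ranges were 11013 to 13207 genes for alpha-, 11294 to 13199 for gamma-tocopherol, 38 to 45 lists in all, 8 to 14 for alpha minus gamma and 0.963 to 0.977 for the correlation. The replicate block gave 11991, 12284 and 0 genes, 41 lists and a correlation of 0.975. Residuals of same-numbered arrays correlated at 0.16, 0.13, -0.08 and -0.37, and no alpha-tocopherol array correlated best with its own number. The fitted dye and compound effects alone make such residuals correlate, with a sign set by the dye orientations of both arrays. Whether the numbers pair the arrays therefore cannot be told from these values. Scaling between arrays left the ratios unchanged by construction. The authors' value table holds the same values as the scanner software's ratio, so these were not separate alternatives, and both enter the totals that follow. Across named genes and alternatives, 101 calls for alpha- and 74 for gamma-tocopherol were lost, and 211 for alpha minus gamma were gained. Signal over background limits gamma replicate 4 most, with 37.8% of Cy3 spots well above background.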

Other observations

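The genes in this part were chosen after their values were seen, as was leaving out the array labelled alpha-tocopherol replicate 4. They are single genes, and no family or group of theirs was tested. The growth factor gene AREG was at 1.90 ± 0.06 and 2.20 ± 0.06 (SE, n = 4; alpha-, then gamma-tocopherol), HBEGF at 1.53 ± 0.22 and 1.43 ± 0.22 and EREG at 1.14 ± 0.07 and 1.24 ± 0.07. The EGF receptor inhibitor ERRFI1 rose by 1.29 ± 0.05 and 1.47 ± 0.05, and the receptor gene ERBB2 fell by 1.41 ± 0.03 and 1.46 ± 0.03. The autophagosome gene MAP1LC3B was at 1.29 ± 0.04 and 1.46 ± 0.04 and the cargo receptor SQSTM1 at 1.12 ± 0.05 and 1.32 ± 0.05. MAFF (1.52 ± 0.04 and 1.74 ± 0.04) and MAFG (1.66 ± 0.04 and 1.85 ± 0.04), which encode small partners of NRF2, rose as well. Falls were seen for the dopa decarboxylase gene DDC at -1.80 ± 0.07 and -1.95 ± 0.07, the lipase inhibitor G0S2 at -1.75 ± 0.05 and -1.99 ± 0.05, fructose bisphosphatase FBP1 at -1.21 ± 0.08 and -1.46 ± 0.08, ketohexokinase KHK at -1.26 ± 0.07 and -1.40 ± 0.07 and the asialoglycoprotein receptor ASGR1 at -1.59 ± 0.03 and -1.69 ± 0.03. All were called in limma for both compounds, with the same direction in all 4 arrays of each.

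Without the array labelled alpha-tocopherol replicate 4, further genes separated the compounds (n = 3 alpha- and 4 gamma-tocopherol arrays). Higher with alpha-tocopherol, having fallen less, were the sterol synthesis genes CYP51A1 (0.63 ± 0.04, adjusted p = 0.00738 in limma) and SQLE (0.52 ± 0.04, adjusted p = 0.00738). The hypoxia-responsive lipid droplet gene HILPDA (0.68 ± 0.05, adjusted p = 0.00738) and ANKRD37 (0.75 ± 0.06, adjusted p = 0.00797) also lay higher. Higher with gamma-tocopherol were the collagenase MMP1 (-0.72 ± 0.06, adjusted p = 0.00929), the early response gene IER3 (-0.68 ± 0.04, adjusted p = 0.00738) and the drug exporter ABCB1 (-0.58 ± 0.09, adjusted p = 0.0318).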
